A study of Homo sapiens with 39 samples.

How the data were processed

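The study measured total RNA of 39 BEAS-2B cultures on Affymetrix whole-transcript arrays, 1 array each. Per the labels' protocols, RNA was extracted with Trizol and cleaned on a Qiagen column, and biotin-labeled cDNA was made with Ambion and Affymetrix kits. The authors deposited a table of log2 expression values for 32321 probe sets, ranging from 1.88 to 14.24. Per the submitters' processing notes, RMA was used; its version was not given in the sources used here. The design text of the series states that values were batch-normalized with ComBat and then set against the control samples of each batch, but whether the deposited values are from before or after ComBat is not stated. The values are absolute levels, so they are from before the step against controls. Array medians lay between 6.41 and 6.62, and correlations between arrays between 0.9515 and 0.9956, so no array was a copy of another. If ComBat was run without the metal as a term, it could have moved levels between batches; its shift of a whole batch cancels in differences within that batch, while its scaling of the spread would alter their size.

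Batches came from the design text. Batch 1 held 6 Cr clones, 3 control clones and 1 parental array. Batch 2 held 3 As, 3 Ni and 3 control clones and 1 parental array, batch 3 held 4 As, 4 Ni and 2 control clones, and batch 4 held 5 V and 3 control clones and 1 parental array. Among the 11 control clones no gene differed between batches (limma; 2.8% of genes had an unadjusted p under 0.05).

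Probe sets were named through the platform annotation, and symbols were updated by Entrez identifier from a RefSeq gene table (assembly GRCh38.p14, used for names and for the order of neighboring genes). Of all probe sets, 19158 had 1 symbol, 1388 had several and 11775 had none, and 19128 matched the gene table. Genes were taken from probe sets with 1 symbol. For 637 genes with more than 1 probe set the one with the highest mean over the 39 arrays was used, which dropped 754 and left 18404 genes. Among called genes with another probe set, one of opposite sign was found for 13 of 60 in As, 9 of 91 in Ni, 8 of 74 in Cr and 5 of 40 in V, and none of these was called the other way. Probe sets of near-identical genes, such as the metallothioneins, the PSG genes and zinc finger paralogs, can share signal, and their changes are uncertain. No filter on dim probe sets was used.

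Each gene was fitted with limma 3.58.1 (R 4.3.3) by lmFit and eBayes on log2 values, with the batch as a fixed term. The 36 clones were fitted together, so that the comparisons shared 1 estimate of the spread (28 residual degrees of freedom, 31.8 with the prior). Parental cells were fitted with the 9 control clones of batches 1, 2 and 4 (8 residual degrees of freedom). Calls used a Benjamini-Hochberg adjusted p of 0.05. Each fold change is given with its standard error from the fit. The difference between the 4 metals was tested with an F test, and the dependence of the As and Ni effects on batch as an interaction.

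The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls per comparison among called genes whose every exposed array lay on the same side of its batch's control mean, with a mean of at least 5 in the higher group and without provisional, microRNA, small nucleolar, olfactory receptor and keratin-associated symbols. It added up to 4 members per gene list with the smallest adjusted p, and for As against Ni and the F test the 10 leading genes. The text names them in rank order and may stop early. Y-linked genes and XIST were tested and counted but are not named.

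There were 30 gene lists with 870 distinct genes, of which 87 were not among the genes tested. Lists were tested with camera at a preset correlation of 0.01, in 150 tests adjusted together. Of these, 21 were called, and 0 of the 21 with an estimated correlation; fry called 9 of the 21 in one direction and 15 as changes in either direction. The 9 held the NRF2 and interferon lists in As clones and the integrated stress and interferon lists in Ni clones. They also held the TGF-beta and mesenchymal lists in Cr clones, and the hypoxia, mesenchymal and matrix protease lists in V clones.

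On simulated data with 200 changed genes among 18404, the As fit recovered 86% of 1.5-fold and 99% of 2-fold changes with 10 false calls. The share at 1.5-fold was 72% for Ni, 63% for Cr, 67% for V, 81% for As against Ni and 54% for parental cells. For the batch interactions it was 9% for As and 5% for Ni.

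Alternatives were all control clones combined without a batch term, parental arrays added to the control clones, only the arrays of a comparison, a filter at the median level, all probe sets, quantile normalization, equal array medians, array quality weights, eBayes with trend and robust options, batch as a random block, leaving out As clones 2 and 5, each batch alone, the clone number as a block, and leaving out each array. Added after the data were seen were fits without As clones 1, 2 and 5 and without X and Y genes. Splits of the arrays within batches were drawn up to 100 times.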

Results

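Gene expression was measured on 39 arrays of BEAS-2B, an immortalized human bronchial epithelial cell line. The series set out to find early changes on the way to cell transformation by 4 metals. Cells had been exposed to 2 µM sodium arsenite for 60 days, 250 µM nickel sulfate for 60 days, 0.5 µM potassium chromate for 60 days or 10 µM sodium vanadate for 30 days. The metal was then withdrawn, single colonies were grown in soft agar for 4 weeks and in monolayer for 3 weeks, and each colony (a clone) gave 1 array. There were 7 As, 7 Ni, 6 Cr and 5 V clones, 11 control clones grown from agar without metal, and 3 arrays of parental cells that never saw agar. The labels do not say whether clones of a metal came from separate exposed cultures, so p-values measure only the spread between clones. Values are log2 expression, and the number of arrays limits the precision. The arrays fell into 4 batches, and every metal was compared with the control clones of its own batches.

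Along the leading component, which held 26% of the variance, V clones lay at 40.6 to 49.3 and Cr clones at -28.5 to -22.8, with control clones between -13.4 and 18.9. Along the next component, which held 18.5%, Ni clones lay at 15.5 to 32.8 and Cr clones at -30.4 to -21.4. As clones lay at 12.9 to 25.3 on it, except As clone 5 at 1.47. As clones 2 and 5 are the ones the submitters called outliers. The array of As clone 2 had the highest median of all, 6.62, against 6.52 or less for the other arrays.

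**Figure D1:**
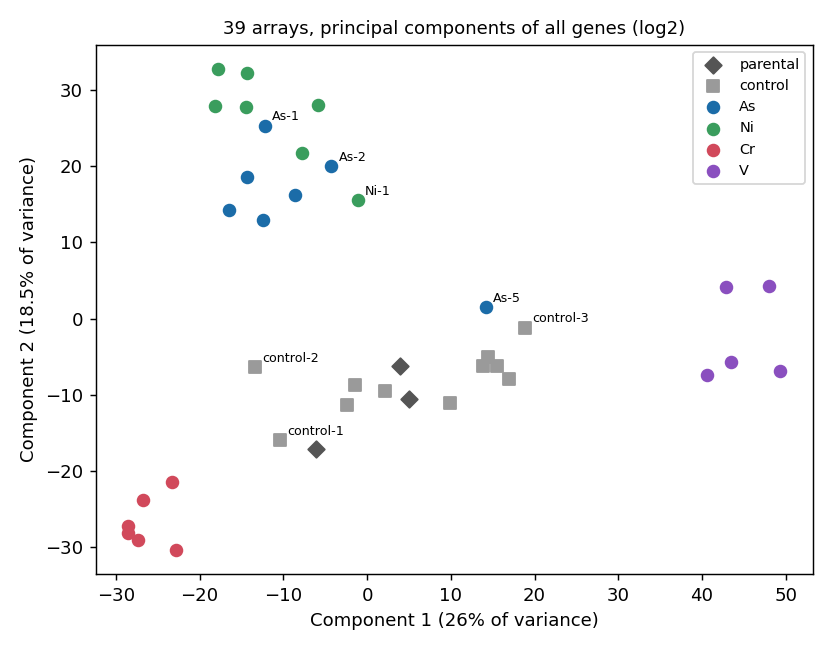
Each point is 1 of the 39 arrays, placed by its scores on the first and second principal components of log2 expression over all genes (axes give the share of variance, 26% and 18.5%), with color for the group. V clones sit at the right, Cr clones at the lower left and Ni clones at the top, and As clone 5 sits near the control clones.

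In As clones the mechanosensitive channel PIEZO2 rose by 2.82 ± 0.38 (log2, SE), from 5.62 ± 0.31 (SD, n = 5) in control clones to 8.43 in 7 As clones (adjusted p = 2.9e-05, higher in 7 of 7 clones). The rule for the largest rises and falls required every clone on the same side, so such counts of clones, here and below, are fixed by it. Parental array 2, of another batch, held PIEZO2 at 7.507, above As clones 4 and 6 at 7.189 and 7.478. The surface peptidase DPP4 rose by 2.56 ± 0.39, the phospholipase LIPH by 2.48 ± 0.44 and FAM171B by 2.43 ± 0.43. GFRA1, a receptor for the growth factor GDNF, fell by 2.57 ± 0.42, the matrix glycoprotein THBS2 by 2.52 ± 0.50, the amino acid transporter SLC38A5 by 2.05 ± 0.48 and DIAPH2 by 2.04 ± 0.38. In all, 1288 of 18404 genes changed, 905 higher and 383 lower, of which 141 changed at least 2-fold.

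Among 37 interferon response genes, 12 rose and none fell in As clones, and 21 rose when adjusted over the list alone. IFI27 rose by 1.28 ± 0.18, IFITM1 by 1.74 ± 0.26 and IFIH1, a sensor of viral RNA, by 1.28 ± 0.27. The list shifted up against other genes (camera adjusted p = 4.6e-10), with adjusted p = 0.48 with an estimated correlation. Of 27 NRF2 antioxidant genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.50 with an estimated correlation). UGDH rose by 0.48 ± 0.12 and CBR1 by 0.49 ± 0.12, a call lost without control clone 5, while SRXN1, which reduces oxidized peroxiredoxins, fell by 0.87 ± 0.21. This call was lost among genes at or above the median level. Of 40 cell cycle genes, 5 fell and none rose (4 rose and 9 fell adjusted over the list alone; adjusted p = 0.00046, and adjusted p = 0.54 with an estimated correlation). The replication clamp PCNA fell by 0.80 ± 0.15, and the mitotic kinesins KIF11 and KIF20A fell by 0.38 ± 0.09 and 0.49 ± 0.13.

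Batch 2 alone called 20 genes and batch 3 alone 29, the fit to As and control arrays alone 483, and the fit without control clone 4 called 823. With all 11 control clones combined the As count was 3303, and after quantile normalization the split was 678 higher and 521 lower (695 and 458 with equal array medians).

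In Ni clones PIEZO2 rose by 3.61 ± 0.38 (adjusted p = 5.5e-07, higher in 7 of 7 clones), the zinc finger gene ZNF716 by 3.03 ± 0.28 and the phosphodiesterase PDE10A by 2.82 ± 0.32. ZNF716 averaged 8.02 ± 0.90 (SD, n = 7) in Ni clones and 4.98 ± 0.34 (SD, n = 5) in control clones. GULP1, an adaptor of apoptotic cell uptake, rose by 2.79 ± 0.72, but this call was lost without control clone 4 or 5. BEX1 fell by 3.25 ± 0.49, HACD4, an enzyme of fatty acid elongation, by 3.21 ± 0.50, the ephrin ligand EFNA5 fell by 3.02 ± 0.57 and the muscle ankyrin protein ANKRD1 by 2.68 ± 0.56. In all, 2098 genes changed, 1198 higher and 900 lower, of which 280 changed at least 2-fold.

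Of the 37 interferon response genes, 11 rose and none fell in Ni clones (19 rose adjusted over the list alone; adjusted p = 1.1e-07, and adjusted p = 0.54 with an estimated correlation). IFITM1 rose by 1.97 ± 0.26, the immunoproteasome subunit PSMB9 by 1.21 ± 0.22 and the peptide transporter TAP1 by 0.78 ± 0.17. Of 27 cholesterol and fatty acid synthesis genes, 6 rose and none fell (7 rose adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.90 with an estimated correlation), including MVD at 0.73 ± 0.15, ACSS2 at 0.85 ± 0.17 and CYP51A1 at 0.68 ± 0.15. That call was lost without control clone 4 or 5 (adjusted p up to 0.091). Of 27 integrated stress response genes, 5 fell and none rose (5 fell adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.48 with an estimated correlation). VLDLR fell by 1.64 ± 0.26, and the chaperone HSPA5 by 0.31 ± 0.08, a call lost without control clone 1. Of 37 extracellular matrix genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.87 with an estimated correlation). The basement membrane genes HSPG2 and LAMC1 fell by 0.86 ± 0.16 and 0.67 ± 0.14, and the collagen gene COL5A2 rose by 1.75 ± 0.38. The matrix call was lost without control clone 2 (adjusted p = 0.083) and among genes at or above the median level.

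Batch 2 alone called 13 genes and batch 3 alone 905. With all 11 control clones combined the Ni count was 4309.

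In Cr clones the desmosomal cadherin DSC3 rose by 5.58 ± 1.0, from 5.56 ± 0.36 (SD, n = 3) in control clones to 11.1 ± 0.19 (SD, n = 6) in Cr clones (adjusted p = 0.00093, higher in 6 of 6 clones). Unexposed arrays varied widely in DSC3: the parental array of the same batch lay at 9.705, parental array 1 at 10.32 and control clones 1 and 2 at 9.298 and 10.13, and the rise was 4.23 with all 11 control clones combined, 4.54 with parental arrays added and 3.69 with batch as a random block. The metalloprotease ADAMTS1 rose by 4.62 ± 0.90, the BMP antagonist CHRDL1 by 4.16 ± 0.72, PSG2 by 4.02 ± 0.82 and STK26 by 3.52 ± 0.66. The transcriptional coactivator EYA4 fell by 4.26 ± 0.63, the collagen gene COL5A2 by 4.11 ± 0.46, the natriuretic peptide receptor NPR3 by 3.64 ± 0.60 and the hedgehog-binding protein HHIP by 3.55 ± 0.48. In all, 2204 genes changed, 1062 higher and 1142 lower, of which 362 changed at least 2-fold.

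Of 25 TGF-beta target genes, 11 fell and none rose in Cr clones (12 fell adjusted over the list alone; adjusted p = 1.9e-06, and adjusted p = 0.21 with an estimated correlation). PMEPA1 fell by 2.14 ± 0.33, the receptor TGFBR2 fell by 1.5 ± 0.25, JUNB by 1.09 ± 0.20 and the latent TGF-beta binding protein LTBP2 by 1.11 ± 0.24. Of 31 mesenchymal transition genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.48 with an estimated correlation). The transcription factors ZEB1 and SNAI1 fell by 1.75 ± 0.26 and 1.17 ± 0.18, and the surface protease FAP by 2.29 ± 0.37. Of 38 NF-kB and inflammation genes, 5 fell and none rose (5 fell adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.87 with an estimated correlation). The endotoxin receptor TLR4 fell by 2.76 ± 0.67 and IL1R1 by 1.30 ± 0.37, a call lost without control clone 6, 7 or 8. The NF-kB list call was lost with all control clones combined and by fry in one direction (adjusted p = 0.18).

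Each of the 3 control clones weighed on the Cr count, which was 1061 without control clone 6, 784 without clone 7 and 1429 without clone 8. With all 11 control clones combined it was 4241, with array quality weights 3894, and with equal array medians the split was 839 higher and 1347 lower.

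In V clones the membrane protein TMEM47 rose by 5.87 ± 0.55, from 6.29 ± 0.095 (SD, n = 3) in control clones to 12.2 ± 1.1 (SD, n = 5) in V clones (adjusted p = 4.4e-08, higher in 5 of 5 clones). Other unexposed arrays held more TMEM47: the parental array of the same batch lay at 8.618 and control clones 5, 7 and 8 at 8.263, 8.154 and 8.891. EYA4 rose by 5.14 ± 0.65, the protease TMPRSS15 by 4.28 ± 0.62, the integrin ligand EDIL3 by 3.91 ± 0.66 and the surface glycoprotein CD24 by 3.81 ± 0.78. DSC3 fell by 5.34 ± 1.1 (DSC3 fell by 4.23 with all 11 control clones combined and fell by 3.84 with batch as a random block), the zinc finger gene ZNF93 fell by 3.68 ± 0.60, ARHGAP28 fell by 3.33 ± 0.62 and the pseudogene ZNF788P fell by 3.26 ± 0.41. In all, 1198 genes changed, 589 higher and 609 lower, of which 345 changed at least 2-fold.

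**Figure D2:**
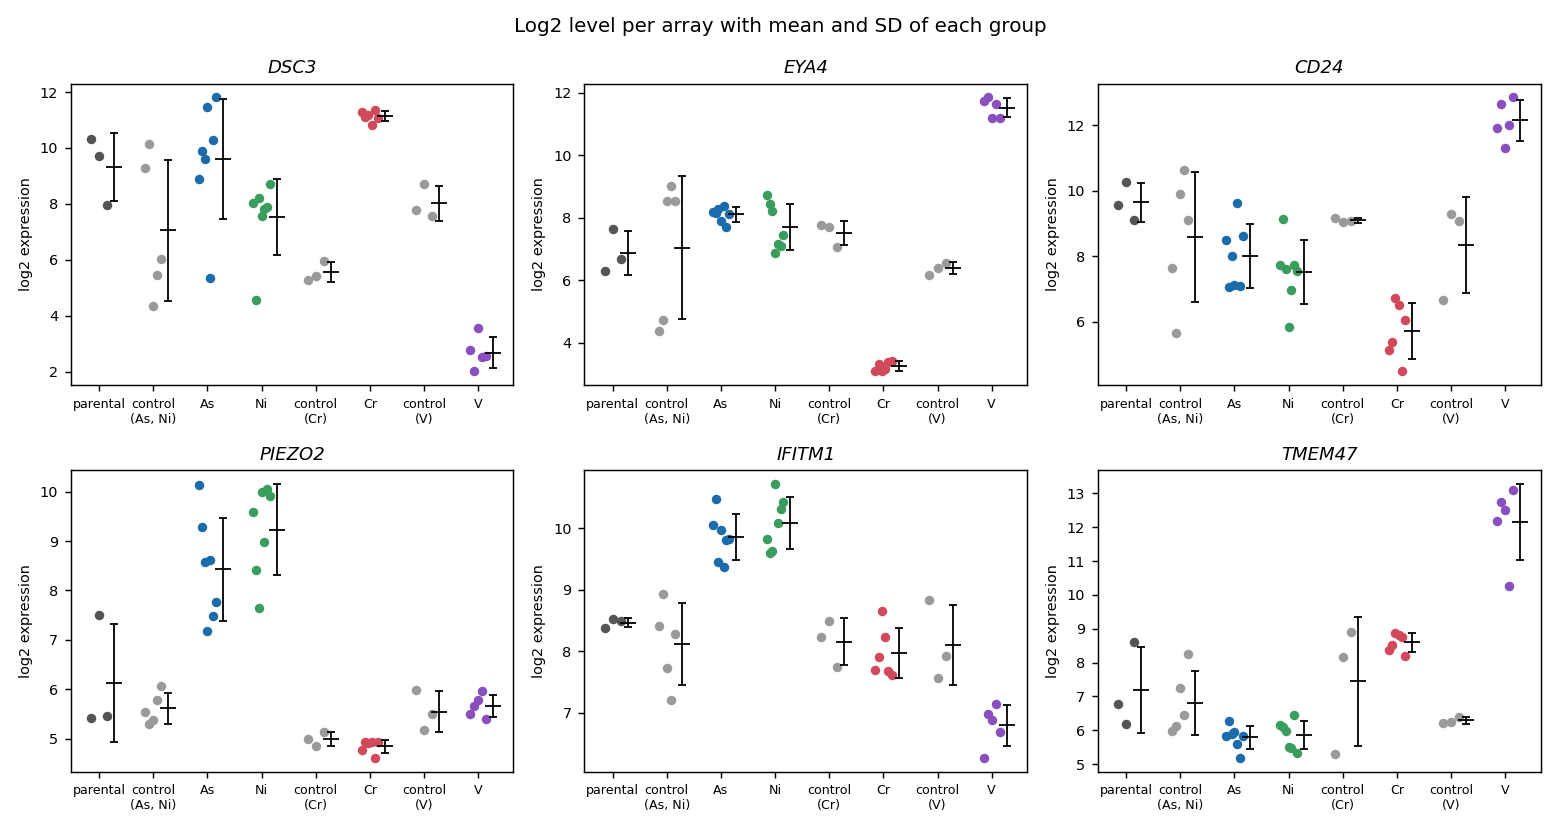
Log2 expression of 6 genes on each array (points), by group on the horizontal axis, with the group mean and SD beside the points. Control clones, which had no metal, are split by the metal clones they were paired with. DSC3 averaged 11.1 in Cr clones and 2.68 in V clones, EYA4 3.25 and 11.5, and PIEZO2 was high in As and Ni clones, at 8.43 and 9.23.

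Of the 31 mesenchymal transition genes, 9 rose and none fell in V clones (12 rose and 1 fell adjusted over the list alone; adjusted p = 3.3e-06, and adjusted p = 0.11 with an estimated correlation). The fibronectin receptor subunit ITGA5 rose by 1.12 ± 0.19 and the matrix crosslinker LOXL2 by 1.04 ± 0.19. Fibronectin itself, FN1, rose by 0.92 ± 0.21, a call lost without control clone 9 or 10. Of 32 hypoxia response genes, 4 rose and none fell (8 rose adjusted over the list alone; adjusted p = 4.9e-06, and adjusted p = 0.54 with an estimated correlation). The carbonic anhydrase CA12 rose by 1.58 ± 0.25 and STC2 by 1.30 ± 0.25. Of 25 matrix proteases and inhibitors, 5 rose and none fell (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.54 with an estimated correlation). MMP16 rose by 1.93 ± 0.35, and the gelatinase MMP2 by 2.10 ± 0.52, a call lost without control clone 10. Of 43 growth factor and MAPK feedback genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.85 with an estimated correlation). The MAPK phosphatase DUSP4 rose by 1.71 ± 0.31, and the list call was lost without control clone 10 or V clone 2 and with all control clones combined.

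Of the 27 cholesterol and fatty acid synthesis genes, 4 fell and none rose in V clones (4 fell adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.91 with an estimated correlation). DHCR7, the last enzyme of cholesterol synthesis, fell by 0.92 ± 0.24, a call lost without control clone 9 or 10 or V clone 5. The list call was lost without V clone 4 (adjusted p = 0.050) and among genes at or above the median level. Of 23 p53 targets, PHLDA3 rose, by 0.66 ± 0.15, and none fell (1 rose adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.94 with an estimated correlation). The PHLDA3 call was lost without control clone 9 or 10, and the p53 list call without control clone 10 or 11 or V clone 2, 3 or 5.

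The V count was 417 without control clone 10 and 725 without control clone 11, and 688 in the fit to V and control arrays alone. With all 11 control clones combined it was 3145, and with equal array medians the split was 753 higher and 477 lower.

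**Figure D3:**
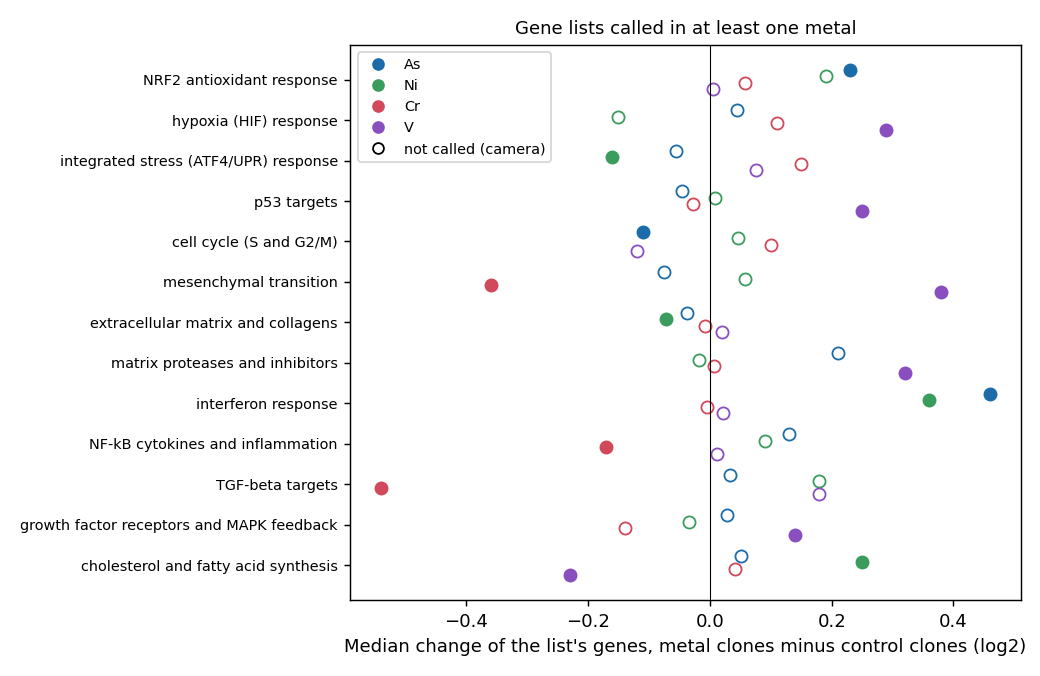
Median log2 change of each gene list (horizontal axis, metal clones minus control clones) for lists that shifted in at least 1 metal; colors stand for the metals, and open circles mark lists that camera did not call. The interferon list lay at 0.46 in As and 0.36 in Ni clones, and the mesenchymal list at -0.36 in Cr and 0.38 in V clones.

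Parental cells were set against control clones to see what growth in agar and cloning alone did on average. Changes that differ from clone to clone average out in this comparison, so it does not reach them. On simulated data it found 54% of 1.5-fold changes. No gene was called (limma, smallest adjusted p = 0.27), and 1053 of 18404 genes, 5.72%, had an unadjusted p under 0.05. DUSP6 differed by -0.93 ± 0.20 and ETV5 by -0.81 ± 0.19 between 3 parental arrays and 9 control clones, both without passing the test. As a list, 27 cholesterol and fatty acid synthesis genes lay higher in parental cells (median 0.23, adjusted p = 6.1e-08, and adjusted p = 0.73 with an estimated correlation). FADS2 differed by 0.69 ± 0.19, and no member passed, also adjusted over the list alone. The cell cycle list lay higher (median 0.07, adjusted p = 0.00096, and adjusted p = 0.90 with an estimated correlation). The p53 list lay lower (median -0.14, adjusted p = 0.0050, and adjusted p = 0.90 with an estimated correlation). The NF-kB list lay lower (median -0.14, adjusted p = 0.024, and adjusted p = 0.90 with an estimated correlation), and so did the growth factor list (median -0.10, adjusted p = 0.017, and adjusted p = 0.90 with an estimated correlation). No member of these 4 lists passed; adjusted over the list alone, 3 growth factor genes were lower. The cell cycle call was lost without parental array 2, the p53 call without parental array 1, the growth factor call without parental array 2 or control clone 6 or 11, and the NF-kB call without parental array 1 or control clone 3, 6, 7 or 8 and with all control clones combined (adjusted p = 0.073), and it turned direction without parental array 2 (adjusted p = 0.58). Without parental array 1, 1 gene passed, and without parental array 3, 2 genes.

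As clones and Ni clones, which shared control clones, differed in 987 genes, 623 higher in As and 364 higher in Ni. BEX1 was 3.50 ± 0.45 higher in As clones (adjusted p = 1.6e-05), HACD4 3.34 ± 0.45, the desmosomal gene DSC2 2.79 ± 0.51, EFNA5 2.74 ± 0.51 and the collagen crosslinker LOX 2.29 ± 0.33. ZNF716 was higher in Ni clones (log2 difference As minus Ni -2.85 ± 0.25, adjusted p = 2e-08), as were PDE10A at -2.48 ± 0.29, SIMC1 at -2.46 ± 0.35 and THBS2 at -2.41 ± 0.45. Batch 2 alone called 1 gene and batch 3 alone 895; the count was 1604 without As clone 1, 630 without As clone 3, 655 without As clone 7, 558 without Ni clone 5 and 621 without Ni clone 7. With equal array medians the split was 476 higher in As and 496 higher in Ni.

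As and Ni clones had 432 genes higher in both and 228 lower in both, where independent lists would share 58.9 and 18.7, and only 2 genes went in opposite directions. PIEZO2 and IFITM1 rose in both, and SLC38A5 fell in both. Across genes, which are not independent replicates, the As and Ni changes correlated at r = 0.62, against 0.59 for unchanged groups simulated on the same control arrays. The same sign was found in 72.3% of genes against 70% simulated, and the covariance was 0.0516 against 0.011. As changes of batch 2 and Ni changes of batch 3, which share no array, correlated at 0.42, and the reverse pair at 0.19.

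The change differed between the 4 metals in 4558 genes (F test, and 10019 with all 11 control clones combined). Cr clones lay only in batch 1 and V clones only in batch 4, each with their own control clones. V exposure lasted 30 days and the others 60 days. So the count cannot tell a difference between metals from one between control clones, batches or exposures. With batch as a random block the count was 15303, which the negative correlation estimated within batches, -0.1, may have inflated. ZNF716 led, at 3.03 ± 0.28 in Ni clones and between -0.17 and 0.20 in the other 3. COL5A2 rose by 1.44 ± 0.38 in As, 1.75 ± 0.38 in Ni and 2.88 ± 0.47 in V clones, and fell by 4.11 ± 0.46 in Cr clones; the As call was lost without control clone 2 or 4. The collagen chaperone SERPINH1 fell by 1.33 ± 0.15 in Ni clones, and IGFL1 fell by 2.33 ± 0.19 in Cr clones. No gene changed in the same direction in all 4 metals, where independent lists would give 0.11 higher and 0.038 lower; 22 genes were called in all 4, and 80 were higher and 38 lower in at least 3. With all 11 control clones combined, 14 genes changed in the same direction in all 4.

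Cr and V changes were opposed. Of the genes called in both, 188 were higher in Cr and lower in V and 222 the reverse, where independent lists would give 35.1 and 36.5, and 11 went the same way. DSC3, EYA4, COL5A2, CD24 and SEMA3A were among the opposed genes. SEMA3A, a guidance ligand, fell by 2.65 ± 0.72 in Cr clones, a call lost without control clone 6 or 7, and rose by 3.08 ± 0.74 in V clones, a call lost without control clone 10. Across genes the changes correlated at r = -0.51, and at -0.12 when set against the parental array of each batch in place of the control clones; the other pairs of metals lay between -0.11 and 0.16, apart from As and Ni.

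**Figure D4:**
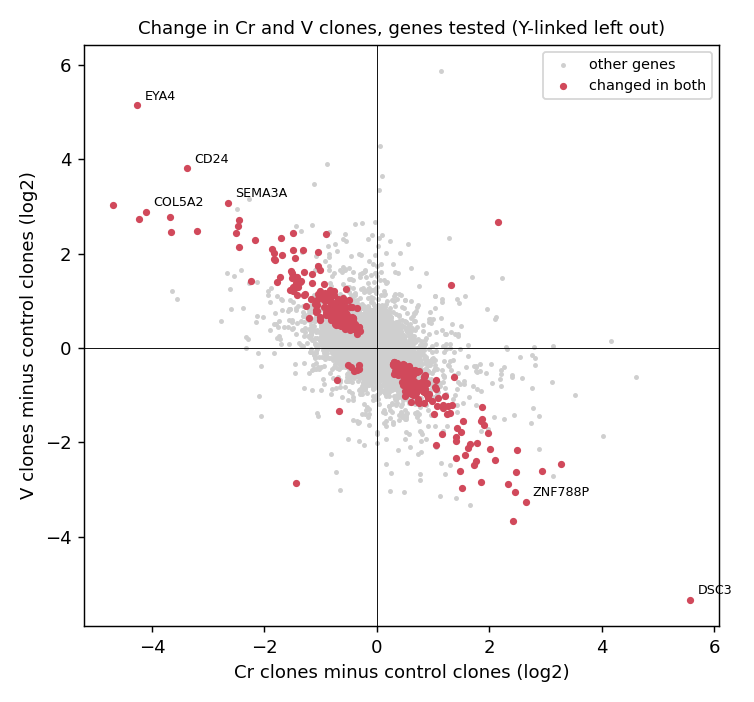
Each point is 1 gene, placed by its log2 change in Cr clones (horizontal) and in V clones (vertical); red marks genes called in both, and Y-linked genes and XIST are left out. DSC3 lies at 5.58 and -5.34, EYA4 at -4.26 and 5.14, and most red points lie in the upper left and lower right.

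The As and Ni clones of batch 2 and batch 3 were compared to see whether the metal's effect depended on the batch. No gene differed for As (limma, smallest adjusted p = 0.23; 1367 genes at an unadjusted p under 0.05) or for Ni (smallest adjusted p = 0.19; 1673 genes). DHCR7 and SREBF2, chosen after their values were seen, had the smallest p for As, at 1.28 ± 0.22 and 1.35 ± 0.24, without passing. The test had little power: on simulated data it found 48% of 2-fold differences for As and 43% for Ni. With 1 array left out, genes passed for As without control clone 3 (24), 4 (7) or 5 (10) or As clone 1 (1), 3 (3) or 6 (1), and for Ni without control clone 3 (131), 4 (7) or 5 (20), As clone 5 (2) or Ni clone 5 (1), and array quality weights called 146 for Ni.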

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

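The tests of chance order of the genes, of gained or lost segments, of regions variable among unexposed clones, of the component of control clones and of exchanged labels were chosen, or changed in form, only after their results were seen. Of 111 array summaries, list means and named genes checked for a clone far from its group, 10 had one, where chance alone flags about 1 in 20. The array of As clone 2 had a median of 6.62 against 6.46 to 6.52 in the other As clones, and As clone 5 scored 14.2 on the leading component against -16.5 to -4.25. In As clone 5, ANO2 lay at -0.464 from the control mean against -2.58 to -1.80 in the others, and VLDLR at -0.158 against -1.82 to -1.18. ZNF716 lay at 0.935 in Ni clone 1 against 2.76 to 4.14. In Cr clone 4, STK26 lay at 4.63 against 3.01 to 3.61 and NOX4 at 2.70 against 3.08 to 3.29. COL5A2 lay at -3.54 in Cr clone 6 against -4.37 to -4.07. ZNF93 lay at -2.40 in V clone 5 against -4.08 to -3.91, and ZNF788P at -3.38 in V clone 4 against -3.25 to -3.21. Differences between groups were tested for the 4 metals, in 4558 genes, and for As against Ni, in 987 genes.

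Other splits of the arrays within batches were refitted. For As the real 1288 genes were the most among 100 splits, and the highest other, 1087, set As clones 1, 2, 3, 4 and 6 against control clones together with As clones 5 and 7. For Ni the real 2098 were the most among 100 (highest other 855), for Cr 2204 among all 84 (27), for V 1198 among all 56 (28) and for the difference between metals 4558 among 100 (365). For each of these 5 counts only 1 split, the real one, gave as many, which argues against a chance division of the clones. The splits treat clones as separate units. Clones of a metal that came from 1 exposed culture could also top them, so a shared origin is not excluded. For As against Ni, 2 of 100 splits gave at least the real 987, which argues against a chance division with the same limit. The highest other, 1847, exchanged As clone 1 and Ni clone 1 and points to a structure of these clones. For parental cells (64 splits, highest other 5) and for genes changed in the same direction by all 4 metals (100 splits, highest other 0) the real count was 0, which every split must reach, so the splits say nothing about chance there.

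As clones 1 and 5 lay apart from As clones 3, 4, 6 and 7, a pattern first set out for clone 5 and widened to clone 1 once the splits had been seen. As clone 2 lay apart in part too: the array it correlated with best was Ni clone 4 (r = 0.9881). No explanation was tested for As clone 2. On the As minus Ni difference of batch 3, As clone 1 scored -15.0, near Ni clones 2 and 3 at -20.8 and -17.7. As clone 3 scored 10.2, and As clone 2 lay in between at -4.8. The midpoint of As clone 3 and the mean of Ni clones 2 and 3 was -4.53. As clone 2 was left out of it and lay just on its Ni side. An exchange with Ni clone 1 would need that clone on the As side of the midpoint. Ni clone 1 scored -6.07, on the Ni side, which would argue against the exchange, but As clone 3 alone stood for As in the midpoint. A margin wider than the control clones' scores (-2.65 to 1.39) was required once the score of Ni clone 1 had been seen. By this margin exchanged labels cannot be told apart from a clone of its own kind. For As clone 5, the slope of its deviations on the As change of batch 2 argues against a plain mislabelled control clone. It was 0.151, above the 0.0675 of the highest of 8 held-out control clones, though below the 0.561 to 0.679 of As clones 4, 6 and 7. Control clones 4 and 5 were each set against the other, so their slopes mirror each other. On the other side, the array As clone 5 correlated with best was control clone 3 (r = 0.9901). Its mean r was 0.9865 with control clones and 0.9815 with As clones. Its array weight of 0.51 lay below the median of 1.1 but was not the lowest, so array quality stays open, as does a real difference between clones.

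Cr and V changes went in opposite directions. Differences in signal distribution between arrays are argued against, since r was -0.51 before and after quantile normalization; scaling of the spread within batches by ComBat was not tested. Against the parental array of each batch in place of the control clones r was -0.12, with 1 parental array per batch. A difference of parental cells from agar clones in general would enter both changes and raise r, whatever the control clones did. So this value does not tell whether the control clones carry part of the opposition over all genes. A candidate explanation is a difference that unexposed clones already have. The leading component of control clones 1 to 5, which shares no array with Cr or V, correlated with the Cr minus V change at 0.52 in size. With the As and Ni changes, which are measured against these same clones, it correlated at 0.087 and 0.058. In 1000 gene permutations the size was at most 0.024, but these treat genes as independent, so that bound is too narrow. Of the 410 genes called in opposite directions, 373 had the sign of this component. Control clones 1 to 5, on which it was built, scored 21.2, 22.9, -30.7, -4.96 and -17.0 on it. Cr clones scored 12.1 to 17.5 and V clones -28.4 to -19.5, with the parental arrays of their batches at 4.90 and 5.24. Control clones 6 to 8 lay at -6.11 to -3.91 and control clones 9 to 11 at 0.586 to 5.06. Parental array 1, of another batch, scored 15.5, within the range of the Cr clones. Whether the metals selected such cells or moved them was not tested.

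Changes of neighboring genes went together, and chance order is argued against: the mean lag 1 correlation along the gene order was 0.215 against at most 0.01 in 100 shuffled orders. Overlapping probe sets or adjacent paralogs are argued against as the only source by a mean lag 10 correlation of 0.112, against at most 0.011. That test cannot reach paralog clusters longer than 10 genes. The higher lag 1 value leaves room for a part from close neighbors. Gained or lost segments in single clones may account for the pattern: in windows of 40 genes found on every other gene, 73.2% of the genes left out moved with their window, against 50.2% in shuffled order, though regional regulation would do the same. Control clones held 0.43 ± 0.099 (SE) as many shifted windows per clone as metal clones (1 each in control clones 6 to 8 against 47 to 88 in Cr clones, but 21 to 57 in the other control clones against 26.7 to 80.5 in As, Ni and V clones), so regions already variable among unexposed clones stay open; the bound of 0.5 was set first, and a margin of 2 SE, without which the pooled ratio would argue against them, was added after the value was seen. Clones were centered on their medians only after a first run without centering, in which As clone 2 had 175 shifted windows, the share was 74.8% and the ratio 0.38 ± 0.093.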

How the results depend on the processing

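Fits without As clones 1, 2 and 5 and without X and Y genes were chosen only after the data were seen. Among 423 named gene results and 9932 refits, no called result changed direction, while uncalled ones could, such as EYA4 in As (-0.743 to 2.31) and Ni clones (-1.63 to 2.57); 1145 refits lost a call and 50 gained one. Results not named below kept counts within 1.5 times; for counts that moved, the cause was not tested unless fewer arrays show it. With all 11 control clones combined and no batch term the counts were 3303 (As), 4309 (Ni), 4241 (Cr), 3145 (V), 10019 (difference between metals) and 14 (same direction in all 4), and 1286 of the 1288 As calls remained. With batch as a random block they were 4289, 5355, 6139, 4780, 15303 and 46, at an estimated correlation within batches of -0.1. A negative correlation makes means of whole batches look more precise than independent arrays would, so these counts may be too high. Parental arrays among the controls gave 1 gene in the same direction in all 4. With fewer arrays, only those of the comparison gave 483 (As), 688 (V) and 294 (As against Ni), batch 2 alone 20 (As), 13 (Ni) and 1 (As against Ni), and batch 3 alone 29 (As) and 905 (Ni). Array quality weights gave 2004 (As), 3894 (Cr), 2002 (As against Ni) and 146 (Ni by batch). The Ni by batch count was 3 with all probe sets and 5 without As clones 2 and 5. Without As clones 1, 2 and 5 the counts were 2075 (As) and 2074 (As against Ni). With each array left out in turn the counts ran from 823 to 1830 (As), 1488 to 2461 (Ni), 784 to 2300 (Cr), 417 to 1175 (V), 0 to 2 (parental), 558 to 1604 (As against Ni), 3835 to 4971 (difference between metals), 0 to 24 (As by batch) and 0 to 131 (Ni by batch); it was 0 throughout for the same direction in all 4. Parental counts were 1 without parental array 1 and 2 without parental array 3. The parental NF-kB list turned direction without parental array 2 (adjusted p = 0.58), and ranged from 6e-07 (without parental array 3) to that value. The As and Ni changes correlated at 0.422 and 0.191 in the pairs of batches that share no control array.

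Clone numbers are shared between groups but did not pair the clones: deviations of same-numbered clones correlated between -0.27 and 0.19, and 4 of 7 As clones correlated best with the Ni clone of their own number. With the clone number as a block the counts were 351 (As), 793 (Ni) and 251 (As against Ni). Batch as a random block was not run for the batch interactions, nor were parental arrays as controls for the parental comparison. Signal over background was not given for these arrays, so which dim genes lay at background is not known here.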

Other observations

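The runs of neighboring genes given here were chosen only after their values were seen. Several gene groups moved in part without a list call. In Cr clones 10 of 37 extracellular matrix genes fell and 2 rose (camera adjusted p = 0.10), with BGN falling by 2.32 ± 0.44 and COL4A1 by 1.30 ± 0.27, and 5 of 37 epithelial junction genes rose and 1 fell (adjusted p = 0.52), with DSC2 rising by 3.28 ± 0.67 and the simple keratins KRT18 and KRT8 by 0.59 ± 0.15 and 0.48 ± 0.12, both calls lost without control clone 7. In V clones 5 of 37 matrix genes rose and none fell (adjusted p = 0.33), with LAMB3 rising by 1.69 ± 0.37, a call lost without control clone 10. Weeks after the metal was withdrawn, of 21 metallothionein and metal homeostasis genes 2 rose and 2 fell in As (camera adjusted p = 0.86; fry for changes in either direction, adjusted p = 0.0016), 4 rose and none fell in Ni (adjusted p = 0.89; fry 0.0059), 2 fell and none rose in Cr (adjusted p = 0.76) and none was called in V clones (adjusted p = 0.91). MT2A fell by 0.40 ± 0.11 and MT1E by 0.85 ± 0.24 in As clones, while MT1F and MT1X rose by 0.79 ± 0.25 and 0.50 ± 0.16 in Ni clones. The MT2A and MT1E calls were lost without control clone 3, 4 or 5 or As clone 3, 4 or 7, the MT1F call without control clone 1, 4 or 5 or Ni clone 2, 4, 5 or 6, and the MT1X call without control clone 1, 2 or 5 or Ni clone 2, 5, 6 or 7. The iron exporter SLC40A1 rose in As and Ni clones, by 1.15 ± 0.26 and 1.08 ± 0.26. In Ni clones IL6 rose by 1.76 ± 0.27, NQO1 by 1.03 ± 0.17 and the histone methyltransferase gene EHMT2 by 0.58 ± 0.08. In V clones INHBA rose by 1.46 ± 0.21 and TGFBR2 by 1.21 ± 0.26, the latter a call lost without control clone 10.

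No list of another cell type or cell line was called in any metal, with adjusted p from 0.24 (endothelial markers, Cr) to 0.90 (neural and melanocytic markers, Cr). Single members moved, such as FAP and POSTN of the fibroblast list, which rose by 2.03 ± 0.31 and 1.68 ± 0.48 in As clones (the POSTN call was lost without control clone 1, 2 or 3 or As clone 1, 4 or 7), and FAP, which fell by 2.29 ± 0.37 in Cr clones. Lists for DNA repair, apoptosis, airway differentiation, embryonic genes, heat shock, histones, chromatin modifiers, oxidative phosphorylation, WNT and xenobiotic metabolism were called in no metal. Their lowest camera adjusted p, for a shift in 1 direction, was 0.064 (WNT, Cr). Members of some did move. In Cr clones 4 of 30 chromatin modifiers rose and 5 fell (fry for changes in either direction, adjusted p = 8.4e-16). In V clones 5 of 33 WNT genes rose and 1 fell (fry adjusted p = 1.3e-08). The embryonic list did not move in any metal by this test (fry adjusted p of at least 0.37).

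Runs of neighboring genes were picked for a median change of at least 0.2 in size. In V clones the 120 genes from KRT32 to SPATA32 on chromosome 17 had a median change of -0.36, 86.7% of them negative, and in Cr clones the same 120 genes had a median of 0.26, 90% positive. In As clones 200 genes from TNP2 to ARMC5 on chromosome 16 had a median of 0.26, and in Ni clones 200 genes from DUSP22 to LINC01556 on chromosome 6 had a median of 0.27. As clones had a run from the same first gene, 80 genes from DUSP22 to FAM8A1 with a median of 0.30. The run from HLA-DPB2 to ZNF76 was found in both, at 0.23 in As and 0.36 in Ni clones. As and Ni clones were set against the same control clones, so runs they share cannot be told apart from a shift in those control clones. Of the called interferon genes, 0 of 12 in As and 0 of 11 in Ni clones lay in such runs. The runs held only 3.49% of the genes placed in order in As and 3.27% in Ni clones. So these counts do not tell whether the interferon rise is separate from the runs. The called members of called lists that lay in runs were ABCC1 and PCNA in As, SLC7A5 in Ni, TPM1 and SMAD6 in Cr, and ERBB2, ACACA and ACLY in V clones.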
